A study of Arabidopsis thaliana with 3 samples.

How the data were processed

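Each sample is total RNA of rosette leaves on 1 one-colour array: 1 wild-type sample and 2 samples of plants expressing AtMYB23SRDX, numbered 41 and 45, all at 2 weeks and in the Col-0 accession, per the labels. The deposited table holds 1 value per feature and sample for 28785 features. The deposited values are read as log2 expression, since they lie between 4.04 and 14.8 with no negative value, as log2 of a scanner's range would. The log base, the array platform, the background correction, the normalization by the authors and any summary over several probes are not given in the sources used here. If the base were another, every fold printed would change, while the order and the tests would stay. The medians of the 3 columns, 5.96, 5.89 and 5.91, lie within 0.1 of each other, and by a rule set before the data were examined they were then kept as deposited.

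Samples were grouped from their titles. A floor was set at the 5th percentile of all values (4.68), and features were kept where the mean over the 3 arrays was at or above the 40th percentile of feature means (5.64), which left 17271. For arrays the number of samples limits the precision. Values at or under the floor numbered 1093 in wild type, 1657 in line 41 and 1568 in line 45. No pair of samples held the same data: at most 24 features had identical values in 2 arrays.

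Gene names came from a table that pairs features with Entrez genes. It named 17579 features by 1 gene, 0 by several and left 11206 unnamed here. Symbols were updated through the RefSeq table of assembly TAIR10.1, which held 17491 of the named features and lacked 88. No genome build is given in the sources used here, so that table served only for names, gene type and gene length, and no coordinates are printed. Of several features of a gene, the one with the highest mean stood for it, which left 16905 features, 9681 of them named genes. In 345 genes with several features past the filter the range of their changes had a median of 0.32, and 0 genes had features 2-fold changed in opposite directions. A second feature of COR15A gave a log2 change of 1.50 against 1.28, a second of LHCB4.2 gave 3.62 against 2.42, and further features of RCA gave 2.34 and 2.06 against 2.04. Close copies such as KIN1 and KIN2, LHCB4.1 and LHCB4.2, or the copies of ribosomal protein genes can share signal on an array.

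The lines were compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, Benjamini-Hochberg, adjusted p under 0.05). The fit has 1 residual degree of freedom, from the lines, and 6.76 prior degrees of freedom, and the median standard error was 0.221. Counts past 2-fold in both lines, in each line and between the lines carry no test. Comparisons that share the wild-type array were set beside 100 simulations of unchanged arrays, with the spread between the lines taken over features of similar signal. All features of similar signal were given the same spread, while real features vary in theirs. Simulated counts past 2-fold and false calls can therefore be too low, and recovery may differ in the data. On simulated data with 200 of 16905 features changed, set up like the comparison of the lines with wild type, limma recovered 61.5% at a log2 change of 1 with 5 false calls, 99.5% at 2 with 3 false calls and 100% at 3 with 0 false calls. In a simulation of lists of 6 genes, camera at an unadjusted p under 0.05 called 50 of 50 lists shifted by a log2 change of 2 and 4 of 50 lists with no shift. The simulated genes were drawn independently, so this does not show camera's error rate for lists of correlated genes.

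In all, 22 gene lists with 366 members were fixed before the data were examined, for the transgene, trichome, flavonoid, phenylpropanoid and lignin, root hair, wall loosening, gibberellin, auxin, jasmonate, jasmonate and ethylene defence, salicylate defence, touch and wound, cold with drought and abscisic acid, heat shock, photosynthesis, flower, clock, glucosinolate, epidermis and cuticle, cell cycle, seed mucilage and reference genes. Of their members 57 were named on the array and 42 were measured past the filter. The 7 lists with at least 3 measured members were tested by camera with a preset correlation of 0.01 and Benjamini-Hochberg over these lists, and the median change was set among 10000 random lists of the same size matched on mean signal. Named genes followed a rule: the 12 higher and 12 lower genes with the greatest change in the line that changed less, among those past 2-fold in both; up to 4 members of each list that passed limma or were past 2-fold in both lines; the 3 members of the trichome and flavonoid lists with the greatest mean change; and the 3 genes with the greatest difference between the lines in each direction. Other list members are given as values.

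Alternatives set beforehand were quantile normalization, centring on the median or on the 75th percentile, no dim filter or one at the 60th percentile, no floor or one at the 20th percentile, eBayes without trend or robust, an adjusted p under 0.10, thresholds of 1.5-fold and 3-fold, an estimated correlation in camera, and each line left out. Removal of the trend with mean signal by lowess (span 0.4), ranking by the wild-type value, leaving out filter and floor together, and lists of 213 cytosolic ribosomal protein genes and of annotated pseudogenes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.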

Results

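Transcript levels were measured on 3 one-colour arrays of 28785 features, each hybridised with total RNA from rosette leaves of Arabidopsis thaliana plants aged 2 weeks, all of the Columbia accession Col-0. Wild type was represented by 1 array. The other arrays held plants numbered 41 and 45, called line 41 and line 45 here, which express AtMYB23SRDX from the 35S promoter. MYB23 is a MYB transcription factor known from trichome initiation, and SRDX is a short repression domain that turns a transcription factor into a repressor of its targets. The median log2 value was 5.96 in wild type, 5.89 in line 41 and 5.91 in line 45. The upper end was lower in wild type, where the 99th percentile was 9.62 against 10.63 in line 41 and 10.54 in line 45. Across features, which are not independent replicates, Pearson's r was 0.981 between the lines, 0.868 between wild type and line 41 and 0.888 between wild type and line 45. The labels give no separate cultures or pools of plants, so p-values measure the spread between the arrays of line 41 and line 45. The lone wild-type array adds nothing to that spread and was assumed to vary like the lines. MYB23 itself is not reported, since no feature was paired with it in the tables used here, so the labels were not checked against the transgene.

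The first question was which genes differed between plants with the chimeric repressor and wild type. The highest rises among named genes were in AT2G25450, known as the dioxygenase GSL-OH of glucosinolate side-chain modification, which rose at least 25.4-fold (log2 change 4.77 ± 0.26 SE as measured, 2 lines against 1 wild-type array), and in GAPC2 (AT1G13440), a cytosolic glyceraldehyde-3-phosphate dehydrogenase, which rose 20.09-fold (log2 change 4.33 ± 0.29). THIC (AT2G29630), an enzyme of thiamine synthesis, rose 17.0-fold and AT3G07230 rose 14.6-fold. AT4G31985, AT1G15930 and AT2G09990, which encode proteins of the cytosolic ribosome, rose 14.5-fold, 13.5-fold and 12.2-fold. AT1G07920, a copy of translation elongation factor EF1-alpha, rose 13.9-fold, and the cold-induced gene KIN2 (AT5G15970) rose 14.2-fold. AT1G52220, listed under the synonym CURT1C for a thylakoid protein, rose at least 8.34-fold, AT1G58684 12.2-fold and AT2G37220 11.7-fold. These are the 12 genes with the greatest rise in the line that changed less, with standard errors of 0.23 to 0.30, and limma's adjusted p lay between 0.000282 and 0.000303 for all 12. Folds given as at least a value belong to genes dim in wild type or in the lines. Their dim side (5.54 in wild type for AT2G25450, 4.92 for AT1G52220) was raised to the dim filter's level of 5.64, since no detection call was used. Such a bound holds for the mean over the lines in the values as deposited, not for each line or other scalings. For AT2G25450 the rise in line 45 as measured, and the mean rise after quantile normalization, were smaller than the bound.

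The falls were smaller. AT4G11410 fell at least 4.32-fold (log2 change -2.23 ± 0.20 SE as measured, 2 lines against 1 wild-type array, adjusted p = 0.000405 by limma). AT4G18500 fell 4.4-fold, AT1G59077 at least 3.85-fold and AT4G22980 at least 3.25-fold. AT5G37590 fell 3.85-fold, AT4G03940 3.72-fold and AT3G10680 3.65-fold. AT4G03840 and AT2G23500, both annotated as pseudogenes, fell 3.54-fold and 3.48-fold. AT3G50320 fell 3.48-fold, AT3G19055 3.47-fold and AT5G04030 3.22-fold. After quantile normalization the log2 change of AT4G18500 went from -2.14 to -2.99 and that of AT4G03840 from -1.82 to -2.49. None of these 12 genes, the greatest falls in the line that changed less, is on a list fixed beforehand, their standard errors were 0.20 to 0.29 and their adjusted p lay between 0.000405 and 0.00213.

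Over the 16905 features tested, 9681 of them named genes, limma called 2468 higher and 1229 lower in the lines at an adjusted p under 0.05, which is 21.9% of the features. Among the named genes 1078 rose and 766 fell. By size alone, with no test, 1652 features were at least 2-fold higher and 243 at least 2-fold lower in both lines, of which 696 and 141 were named genes. Simulated unchanged arrays that share 1 control gave on average 0.44 features 2-fold higher and 0.48 lower in both lines, and 0.09 limma calls. With features of varied spread these numbers could be higher. Of the limma calls 66.8% were higher, against 49.4% after quantile normalization, where 2604 were higher and 2662 lower, and of the features past 2-fold in both lines 87.2% were higher, against 66.3%. Without the filter on dim features, but with the floor kept, limma made 0 calls, with 7167 features at an unadjusted p under 0.05.

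The preset list closest to the known role of MYB23 held genes of the trichome network, and 4 of its 27 members were measured above the dim filter. GIS (AT3G58070), a zinc finger factor that promotes trichome formation, had a log2 change of -0.62 ± 0.23 (adjusted p = 0.0924 by limma, 2 lines against 1 wild-type array). TRY, a single-repeat MYB that represses trichome fate, stood at 0.51 ± 0.24 (adjusted p = 0.170), TBR at -0.44 ± 0.22 (adjusted p = 0.203) and SIM, a cyclin-dependent kinase inhibitor of trichome cells, at -0.11 (adjusted p = 0.773). A further member, MYC1, a bHLH factor, stood at -0.95 in line 41 and -0.64 in line 45, from a wild-type value of 5.95, but its mean lay under the dim filter, so it was not tested. None of the 4 passed over all genes or adjusted over the list alone, and the list median of -0.27 did not stand apart from other genes (camera adjusted p = 0.456); without the dim filter, which adds MYC1, it was -0.44 (adjusted p = 0.372, in a range over alternatives of 0.365 to 0.722). GIS passed after quantile normalization (log2 change -1.06, adjusted p = 0.00494) and after removal of the trend with mean signal (-0.69, adjusted p = 0.0423), within a range over alternatives of 0.00494 to 0.143.

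Genes of flavonoid and anthocyanin synthesis, a pathway that other MYB factors control, gave 5 measured members of 24, and 0 of the 5 passed limma over all genes or adjusted over the list alone. DFR, which encodes dihydroflavonol reductase, had a log2 change of -0.56 ± 0.25 (adjusted p = 0.153), the anthocyanin glycosyltransferase gene UGT79B1 -0.48 ± 0.24 (adjusted p = 0.191) and the malonyltransferase gene 5MAT -0.44 ± 0.20 (adjusted p = 0.162). UGT78D2 stood at 0.42 and UGT75C1 at -0.09. The list median was -0.44, with a camera adjusted p of 0.356. Quantile normalization brought UGT79B1 to -0.68 and an adjusted p of 0.0491, in a range over alternatives of 0.0491 to 0.295.

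Cold-response genes had the lowest camera p of the 7 lists tested. Of 5 measured members of the cold, drought and abscisic acid list of 24, 4 rose, over all genes and adjusted over the list alone. KIN2 rose 14.2-fold (log2 change 3.83 ± 0.30), COR15B (AT2G42530), for a chloroplast protein that protects membranes during freezing, at least 7.27-fold (3.49 ± 0.31 as measured, from a wild-type value of 5.01), the dehydrin gene COR47 (AT1G20440) 3.85-fold (1.94 ± 0.23) and COR15A (AT2G42540) 2.43-fold (1.28 ± 0.30). KIN1, the close copy of KIN2, stood at 0.30 with an adjusted p of 0.495. The list median was 1.94 and camera gave an adjusted p of 0.00138, but adjusted p = 0.568 with an estimated correlation, which rests on 1 residual degree of freedom. COR15A missed the threshold after quantile normalization, with a log2 change of 0.79 and an adjusted p of 0.0517, in a range over alternatives of 0.00234 to 0.205.

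Photosynthesis genes were measured by 3 of 27 list members, and all 3 rose, over all genes and adjusted over the list alone. LHCB4.1 (AT5G01530) and LHCB4.2 (AT3G08940), which encode the antenna protein CP29 of photosystem II, rose 5.68-fold (log2 change 2.51 ± 0.27, adjusted p = 0.000728) and 5.35-fold (2.42 ± 0.33, adjusted p = 0.00204). RCA (AT2G39730), the activase of Rubisco, rose 4.12-fold (2.04 ± 0.26, adjusted p = 0.00146). The list median was 2.42 (camera adjusted p = 0.00227, and adjusted p = 0.568 with an estimated correlation). These are among the brightest features, with wild-type log2 values of 9.53 to 11.90, and among random lists matched on signal the list median lay at percentile 95.01 in line 41 and 84.2 in line 45. After quantile normalization LHCB4.1 stood at 0.80, LHCB4.2 at 1.31 and RCA at 0.53, the median was 0.80 (adjusted p = 0.0434), and after removal of the trend with mean signal 1.42 (adjusted p = 0.0244, and adjusted p = 0.544 with an estimated correlation).

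Of 3 measured genes commonly used as references for expression, 2 rose, EF1A (AT5G60390) by 2.91-fold (log2 change 1.54 ± 0.22, adjusted p = 0.00271) and the ubiquitin-conjugating enzyme gene UBC21 (AT5G25760) by 2.47-fold (1.302 ± 0.22, adjusted p = 0.00557), while TIP41 stood at -0.18 (adjusted p = 0.604). Both rises passed, and TIP41 did not, under each of the 4 other scalings tried. The list median of 1.302 gave a camera adjusted p of 0.134, and lay at percentile 98.4 in line 41 and 99.6 in line 45 of random lists matched on signal. Without the dim filter, which adds SAND at 0.05 in line 41 and 0.0054 in line 45, the median was 0.66.

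**Figure D1:**
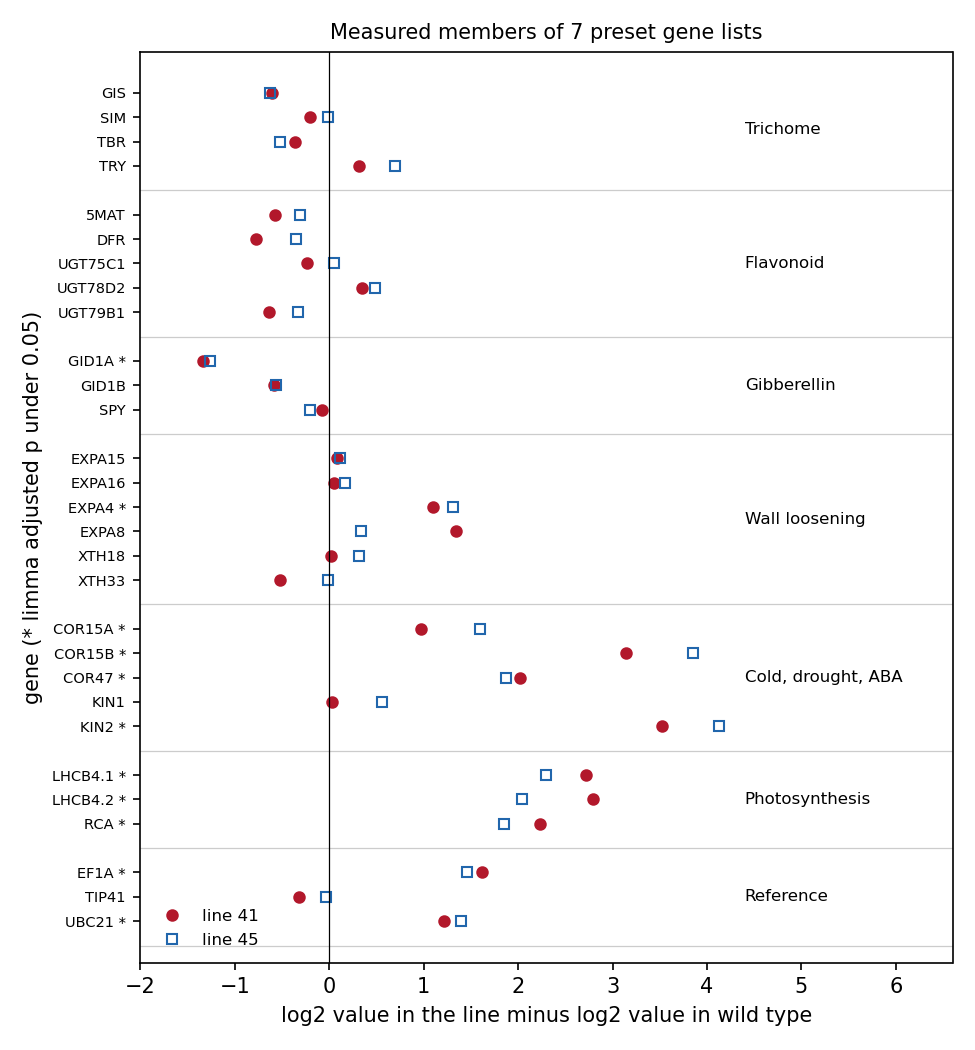
Change against wild type of each measured member of the 7 preset lists with at least 3 measured genes. The horizontal axis is the log2 value in the line minus the log2 value in wild type, as measured and not set to bounds. Filled circles are line 41, open squares are line 45, each point is 1 array against the 1 wild-type array, and an asterisk marks an adjusted p under 0.05 by limma. KIN2 and COR15B, the latter dim in wild type, lie above 3 in both lines and GID1A lies below -1 in both.

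In the gibberellin list, 3 of 21 members were measured and 1 fell over all genes, 2 adjusted over the list alone. GID1A (AT3G05120), a gibberellin receptor, fell 2.46-fold (log2 change -1.30 ± 0.22, adjusted p = 0.00529), while its relative GID1B stood at -0.58 (adjusted p = 0.0981 over all genes) and SPY at -0.14. The list median was -0.58, with a camera adjusted p of 0.127. After quantile normalization GID1B passed over all genes too, with a log2 change of -0.72 (adjusted p = 0.0278, in a range over scalings up to 0.125). Among genes of wall loosening, 6 of 23 were measured and 1 rose, over all genes and adjusted over the list alone. This was the expansin gene EXPA4 (AT2G39700), which rose 2.30-fold (log2 change 1.202 ± 0.23, adjusted p = 0.00859). EXPA8 stood at 1.34 in line 41 and 0.33 in line 45 and did not pass (adjusted p = 0.166). The list median was 0.14, with a camera adjusted p of 0.356.

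The remaining preset lists had 1 or 2 measured members (11 lists) or 0 (4 lists: the transgene, root hair, epidermis and cuticle, and flower genes), so no list test was run on them. BCAT4 (AT3G19710), an aminotransferase of methionine chain elongation in glucosinolate synthesis, rose at least 3.89-fold (log2 change 2.07 ± 0.29 as measured, from 5.53 in wild type, adjusted p = 0.00236), and UGT74B1 of the same pathway stood at 0.84 (adjusted p = 0.0613, and 0.0142 to 0.0599 under the 4 other scalings). The clock gene GI (AT1G22770) rose 2.27-fold (1.18 ± 0.21, adjusted p = 0.0072), and the labels give no time of harvest. The lignin-pathway gene HCT (AT5G48930) rose 2.18-fold (1.12 ± 0.26, adjusted p = 0.0187), but after quantile normalization it stood at 0.21 (adjusted p = 0.492, the highest in a range over alternatives from 0.00409). The subtilase gene SBT1.7 (AT5G67360), known from seed mucilage, rose 1.89-fold (0.91 ± 0.23, adjusted p = 0.0260). Both measured genes of the salicylate defence list fell, WRKY53 (AT4G23810) by 1.81-fold (log2 change -0.86 ± 0.22, adjusted p = 0.0262) and SAG101 (AT5G14930) by 1.7-fold (-0.76 ± 0.22, adjusted p = 0.0422). SAG101 lay at an adjusted p of 0.0503 with neither filter nor floor, in a range over alternatives of 0.00622 to 0.129. HSP17.6C (-0.63, adjusted p = 0.0524), THI2.1 (-0.51), ZAT10 (-0.37), IAA29 (-0.32), PDF1.2c (-0.14) and AUR1 (0.06) did not pass.

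Taken line by line, with no test since each line had 1 array, line 41 had 2115 features at least 2-fold above wild type and 553 at least 2-fold below it, and line 45 had 1809 and 394. KIN2 lay 3.53 above wild type on the log2 scale in line 41 and 4.13 above it in line 45, and COR15B 3.14 and 3.85. LHCB4.2 lay 2.80 above in line 41 and 2.04 in line 45. Both lines shared 1652 features on the higher side, where independent lists of these sizes would share 226, and 243 on the lower side, where they would share 12.9. The lists are not independent, since both use the same wild-type array. Sharing above these numbers therefore does not by itself show like changes in the lines. The changes of the lines correlated with r = 0.932 across features, against 0.501 for simulated unchanged lines sharing 1 control, and the sign was shared by 83.5% of features against 66.7%. The covariance was 0.582, against 0.0453 in the simulation, a difference of 0.536. The control could not be split, and anything particular to the shared wild-type array enters both changes alike. How much of the excess comes from that array, up to all of it, is therefore not known.

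Fewer features separated line 41 from line 45 than separated either from wild type. Of the tested features 83 lay at least 2-fold apart, 57 higher in line 41 and 26 higher in line 45, again with no test. As measured, AT3G15650, AT5G35970 and AT2G04039 were 2.42-fold, 2.398-fold and 2.35-fold higher in line 41. The floral regulator gene UFO (AT1G30950), AT5G07230 and AT5G65207 were, as measured, 2.63-fold, 2.43-fold and 2.27-fold higher in line 45. AT3G15650 in line 45 (5.13), and UFO (5.57) and AT5G07230 (5.43) in line 41, lay under the dim filter's level of 5.64. These folds were not set to bounds. With its dim side raised to 5.64, AT3G15650, at 6.40 in line 41, would not reach 2-fold. AT2G04039 also rose against wild type over both lines (log2 change 1.74 ± 0.44, adjusted p = 0.0269 by limma, 2.36 in line 41 and 1.13 in line 45), and the other 5 did not pass.

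How the difference from wild type went with signal depended on how features were ranked. In the top decile of features by mean signal over the 3 arrays, the median change was 0.60 in line 41 and 0.58 in line 45, and in the dimmest decile -0.13 and -0.10. That mean includes the lines, so a rise moves a gene toward the top: GAPC2 stood at 7.39 in wild type and 11.72 over the lines. Ranked by the wild-type value alone, a ranking added after seeing the data, which leans the other way, the medians were -0.16 and -0.06 in the top decile and 0.44 and 0.40 in the dimmest. LHCB4.1 and RCA were bright in wild type too, at 11.18 and 11.90.

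**Figure D2:**
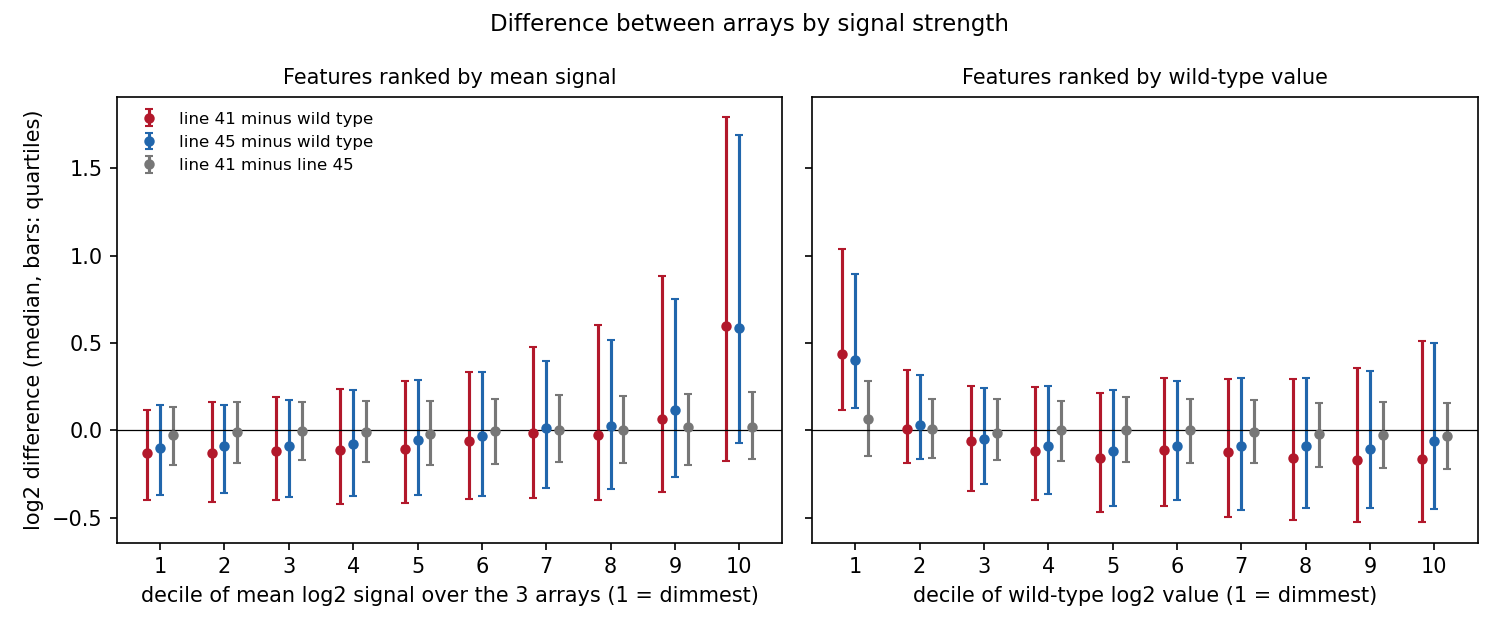
Log2 difference between arrays by decile of signal. The horizontal axis is the decile of mean log2 signal over the 3 arrays (left) or of the wild-type log2 value (right), from dimmest to brightest. The vertical axis is the log2 difference, points are medians over features and bars run from the lower to the upper quartile. The lines lie above wild type in the brightest decile by mean signal but in the dimmest decile by wild-type value, while line 41 minus line 45 stays near 0. In that dimmest decile, features under the dim filter's level in wild type were kept only where the lines were higher.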

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

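No test of the difference was possible for the genes in this part, since each line had 1 array. Among the 52 genes chosen by the naming rule, 4 stood on opposite sides of wild type in the lines. The floral regulator gene UFO had a log2 change of -0.96 in line 41 and 0.44 in line 45, a difference of -1.39. AT5G07230 stood at -0.26 and 1.02, a difference of -1.28, and AT5G65207 at -0.18 and 1.001, a difference of -1.18. AT3G15650 went the other way, with 0.50 in line 41 and -0.77 in line 45, a difference of 1.27. They were named by the rule that takes the genes furthest apart between the lines. The differences are as measured. AT3G15650 in line 45 (5.13), and UFO (5.57) and AT5G07230 (5.43) in line 41, lay under the dim filter's level of 5.64.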

How the results depend on the processing

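Removal of the trend with mean signal, and leaving out filter and floor together, were chosen after seeing the data; all other alternatives were set beforehand. For the named genes 515 of the values were rated the same, 44 lost their call, 41 of these without the dim filter, 3 gained one and 4 turned. The same means an unchanged direction and side of the threshold. Of the 515, however, 51 without line 41 and 49 without line 45 had no test and were compared by direction alone. After quantile normalization limma called 2662 features lower, 713 were 2-fold lower in both lines, 1153 in line 41 and 909 in line 45; the cause was not tested. Without the dim filter limma called 0 higher and 0 lower: with the floor kept, 1069 features had equal values in both lines and the prior degrees of freedom fell to 1.42, against 18 such features and 7.83 with neither filter nor floor, where 2503 were higher and 1894 lower. An adjusted p under 0.10 gave 2017 lower. Without the settings named so far the limma counts lay between 2371 and 2993 higher and between 940 and 1728 lower. At 3-fold in both lines 847 were higher and 18 lower, at 1.5-fold 2663 and 1440, as the threshold itself sets. With an estimated correlation the cold list (median 1.94) and the photosynthesis list (median 2.42) no longer passed, both at an adjusted p of 0.568. Leaving out each line, with no test, gave 1809 to 2115 features 2-fold higher and 394 to 553 lower, 394 without line 41 and 553 without line 45. Without line 41 UFO stood, as measured, at 0.44, AT3G15650 at -0.77, AT5G07230 at 1.02 and AT5G65207 at 1.001. Without line 45 these genes stood, in the same order, at -0.96, 0.50, -0.26 and -0.18, so UFO turned without line 41 and the others without line 45. With 1 line left limma has no residual degrees of freedom, so its counts have no such value, and the lone wild-type array could not be left out. The deposited values with no further scaling are the values used throughout. MYB23 had no value under any setting. No paired analysis was possible because the groups share no replicate numbers. No detection calls were used here, so how far dim features lie above background is not known.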

Other observations

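The lists of ribosomal protein genes and pseudogenes, the test of scale by quantile normalization and the test of the ribosomal genes against the trend were chosen after the results were seen; the tests of gene length, pseudogenes, other splits and the cold list against the trend were written down beforehand.

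Genes of the cytosolic ribosome were higher in both lines as a group. Of 159 measured members of a list of 213, limma called 108 higher and 0 lower, 88 were at least 2-fold higher in both lines, and 51 were not called. The median log2 change was 1.32, which is 2.498-fold, with quartiles of 0.58 and 2.12 (camera adjusted p = 1.7e-29, and adjusted p = 0.165 with an estimated correlation). Under quantile normalization the median was 0.92, with 95 called higher and 4 lower. RPL39C (AT4G31985), RPS12A (AT1G15930) and RPS16A (AT2G09990) belong to this list and also to the 12 greatest rises.

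Many features, among them GAPC2, RCA and LHCB4.1, were at least 2-fold higher in both lines than in wild type, and 3 technical readings were set against an effect of the transgene. A monotone difference in scale between the arrays would vanish under quantile normalization, but 1404 features were at least 2-fold higher in both lines there, against 1652 before and 56 that far apart between the lines, which argues against scale as the whole cause for the set, though RCA went from a log2 change of 2.04 to 0.53 and LHCB4.1 from 2.51 to 0.80. Loss or breakage of RNA by transcript length was examined through gene length, which only stands in for it. Apart from ribosomal protein genes, the genes 2-fold higher in both lines were longer than genes of the same signal by 0.132 on the log2 scale (interval 0.0677 to 0.202). That difference is below the 0.5 set for such a cause and within the 0.2 set against it. The interval, over 1000 draws of random matched genes, lies above 0 and reaches just past 0.2. A small difference in gene length was thus seen, and a small effect of length stays open. Of the 3 ways to set 1 array against the other arrays, 1, wild type alone, gave 3697 calls, and the highest other gave 0 (84 features at an unadjusted p under 0.05 for line 41 alone, 26 for line 45 alone), and 3 splits are too few for a share under 0.05. Setting a line alone also places wild type with the other line, so the distance of wild type enters the residual spread. Few calls there follow from that distance, whatever its cause. An effect of the transgene and anything else particular to the single wild-type sample or its array cannot be told apart here.

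Annotated pseudogenes were lower in the lines. Over all 968 pseudogene features the median log2 change was -0.229 in line 41 and -0.182 in line 45 (95% bootstrap upper bounds -0.199 and -0.163), against -0.0918 and -0.0643 for 15861 protein-coding genes. A raised background in the wild-type array, from labelling or from genomic DNA in the RNA, would also give such a fall. The fall was the pattern itself, so its sign does not separate causes. A uniform background would lift features of equal signal alike. The 435 pseudogenes past the dim filter stood at -0.356 in line 41 and -0.269 in line 45. The central 95% of random lists matched on signal began at -0.124 and -0.083. The random lists could hold features that rose in the lines, as 2468 of the 16905 tested features did, against 5 of the 435. Such rises lift the medians of the random lists. The comparison therefore does not settle whether a uniform background was the whole cause for these 435. Among the 435 past the dim filter 79 fell and 5 rose (camera adjusted p = 3.0e-10, and adjusted p = 0.189 with an estimated correlation), against 133 and 7 of 436 after quantile normalization (camera adjusted p = 3.2e-09), and with the trend with mean signal removed the median was -0.23 against -0.30. Wider transcription of silent loci in wild type than in the lines was not tested.

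The trend with mean signal could have carried the cold-response genes and the cytosolic ribosomal protein genes. The cold list lay at percentile 97.52 of random lists matched on signal in line 41 and 97.71 in line 45, and with the trend removed its median was 1.87 (camera adjusted p = 0.0011, and adjusted p = 0.544 with an estimated correlation, against 0.568 before the removal). The ribosomal list lay at percentile 100 in both lines, and with the trend removed its median was 1.1996 (camera adjusted p = 1.3e-25, and adjusted p = 0.080 with an estimated correlation). The cold list cleared the central 95% of its random lists only narrowly, with a median of 2.016 against an upper bound of 2.014 in line 41. In line 45 these were 1.872 and 1.846, so the matched lists alone do not settle the question for the cold genes. For the ribosomal list the percentile and the size of the shift after removal argue against the trend as the whole cause. For the cold list the removal does not settle it either, since it takes out only the central trend. The spread of change among bright features stays, with an interquartile range of 1.97 in line 41 in the top decile by mean signal before removal. Different growth, temperature or harvest time of the wild-type plants was not tested and stays open beside the transgene.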
